A study of Sesbania grandiflora with 21 samples.

How the data were processed

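Leaves of Sesbania grandiflora, a legume tree, were profiled by RNA sequencing in 21 libraries, each made from messenger RNA enriched on oligo(dT) beads, per the labels' protocols. The sample titles place the libraries in 7 groups of 3, labelled ck, DS-L, DS-S, Y-L, Y-S, DS+Y-L and DS+Y-S. The labels do not expand these letters. The series title names combined drought and salt stress, and which letters stand for which stress is not given in the sources used here. The design text of the series speaks of 4 groups of 3, and the groups were taken from the sample titles instead. Because no label states that the libraries of a group came from separate plants, every p-value measures the spread between these libraries, which may be technical.

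The authors deposited 1 table of counts per assembled gene, whole numbers per the file headers and values, with 97500 gene identifiers in the Trinity style of a de novo assembly. The authors also deposited an FPKM value beside each count, per the file headers. The counting program, its version, the filters and the annotation are not given in the sources used here, and whether estimated counts were rounded to whole numbers is not given either. The identifiers come without gene names or descriptions, so at most 2 identifiers that rose and 2 that fell are printed. For the same reason the 35 gene lists and 7 marker lists fixed before the data were examined could not be used, because 0 genes matched a description. FPKM values served only to derive an effective length per gene, the length implied by its counts, its FPKM values and the library totals. Genes built by de novo assembly can share reads with close copies or allelic variants, so any single identifier may carry part of the reads of a relative.

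Total counts per library ran from 16431940 to 20138058. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with the filterByExpr function by group, which left 38211 genes, and libraries were scaled by TMM. Quasi-likelihood fits (glmQLFit and glmQLFTest) used all 21 libraries and 7 groups, so that every contrast shared 1 estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.383, a coefficient of variation of 0.619 between libraries of a group. The median standard error of a log2 fold change ran from 0.76 to 0.77 for contrasts of 2 groups of 3. CPM values are scaled by TMM, and log2 CPM values used a prior count of 2.

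The comparisons fixed before the data were examined were the 7 groups together, each treated group against ck, the combined label against each of its parts at the same suffix, suffix L against suffix S within each treatment, and the departure of the combined label from the sum of its parts. A further 7 contrasts were run after the data were seen. They were suffix L against suffix S averaged over the 3 treatments, all treated groups against ck, and 5 contrasts averaged over both suffixes, namely DS, Y and DS+Y against ck, and DS+Y against DS and against Y. The rule for named genes was also fixed beforehand. It took, over all contrasts, the 2 largest rises and 2 largest falls among called genes with a log2 fold change of at least 1, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups.

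The procedure was tested on simulated counts drawn from these genes' means, spreads and library sizes, for DS+Y-L against ck with 36686 genes and 50 changed genes at each fold. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery among genes of lower counts was not tried. Each gene was drawn independently of the others, so differences between libraries that many genes share were not simulated. The rates below hold for such counts only, and the false calls in the real libraries may differ. At the estimated spread the procedure recovered 2% of genes changed 2-fold, 44% at 4-fold, 78% at 8-fold and 84% at 16-fold. There were 5 false calls among 109. With a spread of 0.01 it recovered 100% at every fold, with 12 false calls among 212 on 34140 genes.

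Libraries of a group were compared pairwise before averaging. Chi-square per degree of freedom over genes ran from 30.6 to 181, so no pair differed by as little as sampling noise. The share of variation between groups was the between-group part of the squared distances of log2 CPM profiles, tested by 100000 permutations of the group labels.

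Alternatives fixed before the data were examined were DESeq2 size factors within edgeR, no filter beyond a total count above 0, DESeq2 1.42.0 (Wald test, or likelihood ratio test for the 7 groups), a log2 fold minimum of 1, the replicate number as a block, only the 6 libraries compared, and leaving out in turn each library that is part of a comparison. A limma 3.58.1 voom fit with library weights, a robust estimate of the spread in edgeR, and the removal of DS+Y-S replicate 1 from contrasts it is not part of were added after the data were seen. Further computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.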

Results

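The series measured transcript levels in leaves of Sesbania grandiflora under single and combined treatments, with 3 libraries in each of 7 groups and ck as the group against which treatments were set. Every library held between 16431940 and 20138058 counts. Between 47279 and 61454 assembled genes had at least 1 count in each of 20 libraries. DS+Y-S replicate 1 was the exception, with 36755 genes from 17205301 counts.

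**Figure D1:**
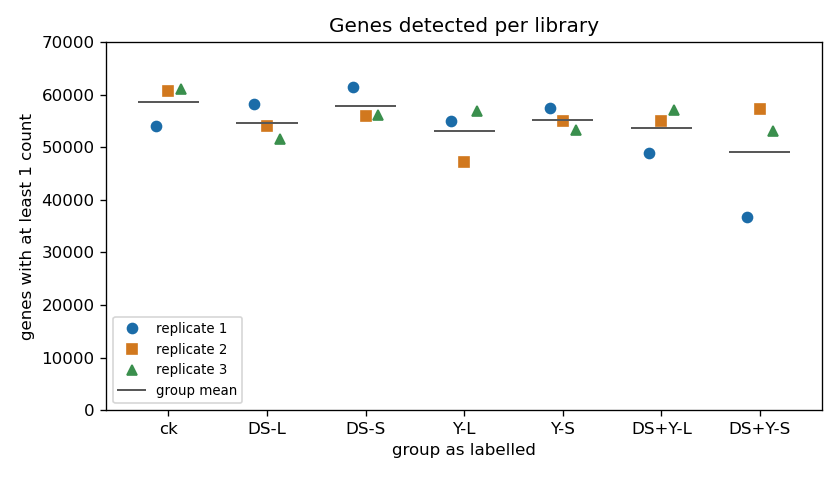
Genes with at least 1 count (y axis) in each of the 21 libraries, by group (x axis); marker shapes give the replicate number and lines the mean of each group. DS+Y-S replicate 1, at 36755 genes, lies below the other 20 libraries, which hold 47279 to 61454.

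Genes differing among the 7 groups were sought first. edgeR called 32 of the 38211 genes tested, and 31 of the 32 had their highest group mean in DS+Y-L. In 30 of the 32, the 2 highest of all 21 libraries were DS+Y-L replicates 1 and 2. The lowest group mean fell in ck for 11 of these genes and in DS-S for 8. The call moved when single libraries were left out, in fits that applied the filter again and tested 41105 to 41737 genes. It dropped to 2 genes without DS+Y-L replicate 1 and to 2 without replicate 2, and stood at 558 without replicate 3. It lay between 10 and 20 when replicate 1 or 2 of ck, DS-L, DS-S, Y-L or Y-S was left out. It was 56 without DS-L replicate 3, 60 without Y-S replicate 3, and 81, 49 and 166 without DS+Y-S replicates 1, 2 and 3. At an unadjusted p under 0.05, 4424 genes passed, which is 11.6% of those tested. Chance passes a share of 0.05 of genes at this threshold on average, here and in the contrasts below. In 3 of 25 assignments of the group labels, the real one included, as many passed, with 4959 the highest other. DESeq2's likelihood ratio test called 2245 genes, limma-voom with library weights 4247 and edgeR without a low-count filter 9331.

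Group labels held 35.9% of the variation between expression profiles, against 30% on average when labels were permuted (permutation p = 0.0463, 100000 permutations, one-sided). Without DS+Y-S replicate 1 the share was 40.04% against 31.6% (permutation p = 0.0216). The most similar library came from the same group for 6 of the 21 libraries, where 2.07 are expected by chance (permutation p = 0.0374). This structure was tested after the data were seen.

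DS+Y-L against ck set the combined label at suffix L against ck, and was the only contrast of 2 groups in which edgeR called genes. The label ck has no suffix, so contrasts against ck cannot tell the treatment from what L or S stands for. In DS+Y-L against ck it called 26, of which 19 rose and 7 fell. Their absolute log2 fold changes ran from 1.64 to 10.34, with a median of 3.14. The 3 DS+Y-L libraries lay entirely above or below the 3 ck libraries in all 26, an arrangement chance gives to 10% of genes and which 23.2% of all tested genes showed.

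The largest rise was in TRINITY_DN45062_c0_g1, at 254 ± 224 CPM in DS+Y-L and 0.185 ± 0.245 CPM in ck (SD, n = 3 each). Its log2 fold change was 10.34 (SE 1.68, edgeR adjusted p = 0.0398). The rise was uneven, because the 3 DS+Y-L libraries ran from 1.21 to 428 CPM, and no other group's mean exceeded 0.3001 CPM. TRINITY_DN26884_c0_g1 stood at 88.9 ± 57.2 CPM in DS+Y-L, from 23.6 to 130 CPM over its libraries, and at 1.31 ± 0.153 CPM in ck (SD, n = 3 each). Its log2 fold change was 6.07 (SE 0.79, edgeR adjusted p = 0.0133). The same gene averaged 18.7 CPM in DS-L, 12.9 in DS-S, 8.28 in DS+Y-S, 8.23 in Y-S and 4.35 in Y-L, with edgeR adjusted p from 0.158 to 1 against ck.

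Among called genes averaging 5 CPM or more in ck or DS+Y-L, the largest falls were in TRINITY_DN3050_c1_g1 and TRINITY_DN651_c1_g1, while a gene of lower counts fell further, from a mean of 3.87 CPM to 0.115 CPM. TRINITY_DN3050_c1_g1 fell from 19.8 ± 12.7 CPM in ck to 2.01 ± 0.818 CPM in DS+Y-L (SD, n = 3 each), a log2 fold change of -3.29 (SE 0.59, edgeR adjusted p = 0.0398). Its means were 4.69 CPM in DS-L, 9.67 in Y-L, 8.60 in DS+Y-S, 21.3 in DS-S and 21.4 in Y-S, none past the threshold against ck (edgeR adjusted p from 0.321 to 1). TRINITY_DN651_c1_g1 fell from 143 ± 13.7 CPM in ck to 16.01 ± 8.43 CPM in DS+Y-L (SD, n = 3 each), a log2 fold change of -3.16 (SE 0.58, edgeR adjusted p = 0.0465). It averaged 36.3 CPM in DS-L, 34.2 in Y-L, 45.7 in Y-S, 38.2 in DS+Y-S and 117 in DS-S, with edgeR adjusted p from 0.33 to 1 against ck.

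**Figure D2:**
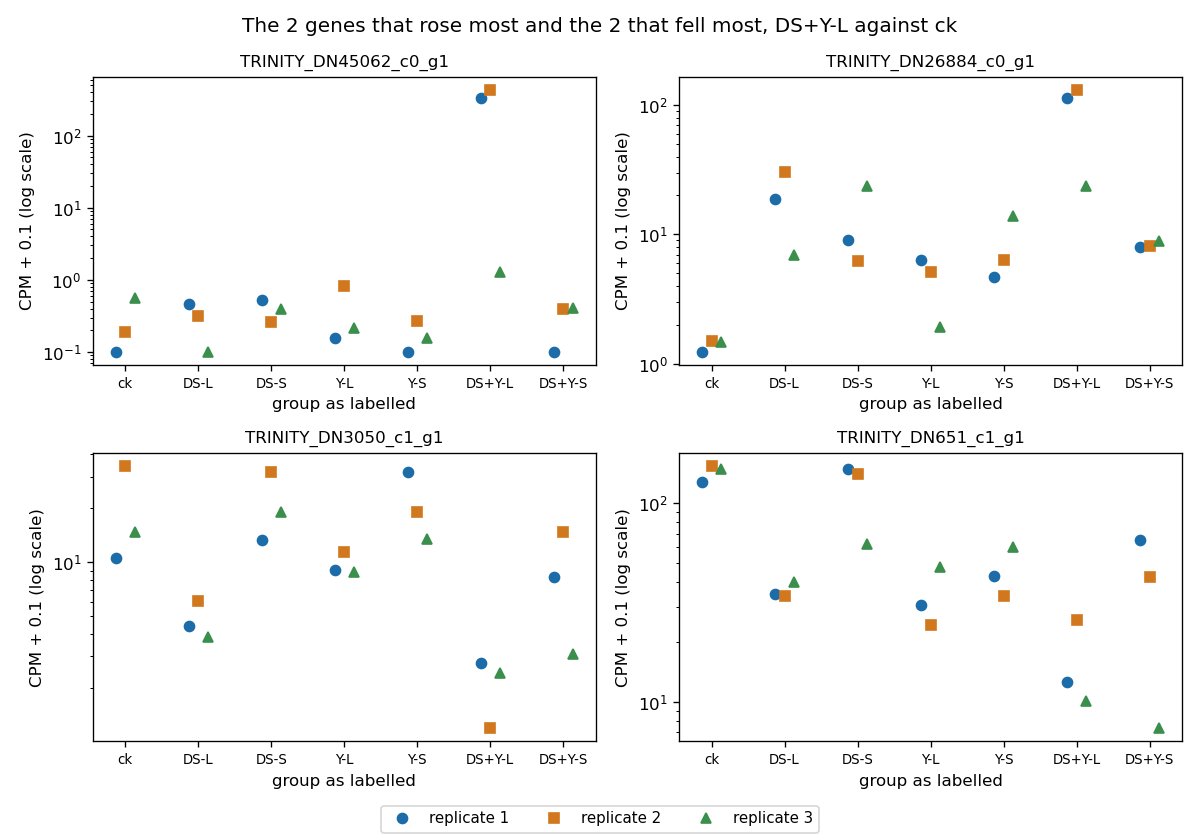
CPM + 0.1 (log y axis) of the 4 named genes in each of the 21 libraries, by group (x axis), with marker shapes for the replicate number. TRINITY_DN45062_c0_g1 reached 428 CPM in 1 DS+Y-L library and 1.21 CPM in another, while TRINITY_DN651_c1_g1 averaged 143 CPM in ck and 16.01 CPM in DS+Y-L.

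The count of 26 moved in fits that left out single libraries. Those fits applied the filter again and tested 41105 to 41730 genes, against 38211 in the main fit. No fit left out 1 library with the main fit's genes kept, so the move from 26 was not separated from the change of genes. Among the fits themselves, on similar numbers of genes, the count ran from 0 to 1735 with the library left out. Leaving out any 1 ck library left 0 calls, leaving out DS+Y-L replicate 1 left 1 and replicate 2 left 2. Leaving out DS+Y-L replicate 3 gave 1735 (932 higher and 803 lower), among them all 26. Of the 1735, 1710 pass the main fit's filter and 25 do not, so most were also tested in the main fit. Leaving out DS+Y-S replicate 1, a library outside this contrast and a choice made after the data were seen, gave 45, again with all 26. DESeq2 called 2795 genes, limma-voom with library weights 2946 and edgeR without a low-count filter 3930, each including all 26. Of the 3930, 3814 pass the filter, so most were also tested in the main fit. Without the filter TRINITY_DN45062_c0_g1 had an edgeR adjusted p of 3.99e-52, against 0.0398 in the main fit from the same libraries. Whether the spread estimated without the filter holds was not tested. A fit to these 6 libraries alone called 0 and left the 4 named genes at edgeR adjusted p from 0.0701 to 0.0965. At an unadjusted p under 0.05, 6923 genes passed in edgeR, 18.1% of those tested.

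The single treatments and DS+Y-S against ck gave no calls in edgeR. Without a low-count filter edgeR called 1601 genes for DS-L, 762 for DS-S, 1274 for Y-L, 615 for Y-S and 1525 for DS+Y-S, and fits to the 6 libraries compared called 7 for DS-L, 8 for Y-L, 8 for Y-S and 0 for the other 2. For DS-L, 3214 genes passed an unadjusted p under 0.05, DESeq2 called 493 and limma-voom with library weights 4670, a count reached with a weight of 12.8 on DS-L replicate 1. Leaving out DS-L replicate 3 gave edgeR 15 calls, all higher. For DS-S, 1228 genes passed the unadjusted threshold (3.21% of those tested), DESeq2 called 97 and limma-voom 0. For Y-L, the corresponding numbers were 3794 unadjusted, 274 by DESeq2 and 2 by limma-voom. For Y-S they were 1216 (3.18% of those tested), 79 and 0. The unadjusted shares of DS-S and Y-S lie below the 0.05 that chance gives. For DS+Y-S they were 3203, 355 and 1, and edgeR called 1 gene once DS+Y-S replicate 1 was left out. The median absolute log2 difference from ck was 0.66 in DS+Y-L, 0.58 in Y-L, 0.53 in DS+Y-S, 0.50 in DS-L, 0.39 in Y-S and 0.37 in DS-S. All 6 treated groups averaged against ck, a contrast added after the data were seen, gave 0 calls in edgeR with a smallest adjusted p of 0.0658, 3491 genes at an unadjusted p under 0.05, 415 calls in DESeq2, 290 in limma-voom and 2259 in edgeR without a low-count filter. Leaving out 1 library raised that 0 to 26 without DS-S replicate 1, 22 without Y-S replicate 1, 14 without DS+Y-S replicate 3, 8 without Y-L replicate 3, 7, 6 and 3 without ck replicates 2, 3 and 1, 3 without DS+Y-L replicate 3, and 1 without DS+Y-L replicate 2 or DS+Y-S replicate 2.

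The combined label against each of its parts asked what the second treatment added to the first. edgeR called 0 genes in all 4 contrasts, and without a low-count filter 2026 for DS+Y-L against DS-L, 1733 against Y-L, 1000 for DS+Y-S against DS-S and 692 against Y-S. For DS+Y-L against DS-L, 4030 genes passed an unadjusted p under 0.05, with 646 calls in DESeq2 and 4104 in limma-voom. For DS+Y-L against Y-L these numbers were 3875, 435 and 22. Leaving out DS+Y-L replicate 3 gave edgeR 500 calls against DS-L and 438 against Y-L. For DS+Y-S against DS-S, 2190 genes passed unadjusted (5.73% of those tested), with 40 calls in DESeq2 and 1 in limma-voom. For DS+Y-S against Y-S, 1807 passed (4.73%), with 18 and 1.

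Suffix L against suffix S within a treatment also gave 0 calls in edgeR, and without a low-count filter 499 for DS, 308 for Y and 1612 for DS+Y. DS-L against DS-S had 1755 genes at an unadjusted p under 0.05 (4.59% of those tested), 91 calls in DESeq2 and 4094 in limma-voom. For this contrast edgeR called 2 without DS-L replicate 3. Y-L against Y-S had 1139 genes unadjusted (2.98% of those tested), 15 calls in DESeq2 and 0 in limma-voom. DS+Y-L against DS+Y-S had 4090, 482 and 0, and edgeR called 211 without DS+Y-L replicate 3. The contrast of L with S averaged over the 3 treatments, added after the data were seen, gave 0 in edgeR, 4625 genes unadjusted, 539 in DESeq2, 979 in limma-voom and 1561 in edgeR without a low-count filter. It gave 30 without DS+Y-L replicate 3, 24 without DS+Y-S replicate 3, 22 without Y-S replicate 3 and 3 without DS-L replicate 3.

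The 5 contrasts averaged over both suffixes, run after the data were seen, gave 0 calls in edgeR as well. Without a low-count filter it called 1469, 1124 and 3046 genes for DS, Y and DS+Y against ck, 2223 for DS+Y against DS and 1910 against Y. For DS, Y and DS+Y against ck, 2370, 2698 and 5639 genes passed an unadjusted p under 0.05. DESeq2 called 309, 232 and 1290 genes in these contrasts, and limma-voom 479, 1 and 443. For DS+Y against DS and against Y, 4306 and 4612 genes passed the unadjusted threshold, with 717 and 622 calls in DESeq2 and 966 and 86 in limma-voom. Without DS+Y-L replicate 3, edgeR called 87 genes in DS+Y against ck, 489 against DS and 361 against Y. It called 1 in DS+Y against ck without DS+Y-L replicate 2, and 1 against DS without DS+Y-S replicate 1.

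Whether the combined label departed from the sum of its parts was tested at each suffix, with ck serving both. edgeR called 0 genes at suffix L (2356 at an unadjusted p under 0.05, 81 by DESeq2, 1 by limma-voom, and 88 in edgeR without DS+Y-L replicate 3). It called 0 at suffix S (1694, which is 4.43% of those tested, 55 and 0). Without a low-count filter it called 818 at L and 729 at S. The median standard error of these contrasts was 1.08 at L and 1.07 at S on the log2 scale. At suffix L the log2 departures were 9.71 (SE 2.32) for TRINITY_DN45062_c0_g1, 0.53 (SE 0.92) for TRINITY_DN26884_c0_g1, -0.19 (SE 0.75) for TRINITY_DN3050_c1_g1 and 0.89 (SE 0.76) for TRINITY_DN651_c1_g1, with edgeR adjusted p from 0.803 to 0.987. At suffix S they were 0.66 (SE 2.42), -3.28 (SE 0.93), -1.42 (SE 0.75) and 0.04 (SE 0.75) in the same order, each with edgeR adjusted p = 1. Across 38211 genes, which are not independent replicates, the change on adding Y to DS-L correlated with the change from ck to Y-L at r = 0.262. Adding DS to Y-L against DS-L alone gave r = 0.259. At suffix S the values were 0.0267 for adding Y and -0.0294 for adding DS. These pairs of contrasts share no library. The regroupings of the 12 libraries used mean log2 CPM in place of fitted changes. By that measure the 4 values were 0.297, 0.268, 0.0164 and -0.0289, all inside the central 95% of 1000 regroupings.

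Libraries of 2 kinds stood apart from the rest. The leading axis of variation over the 20 libraries other than DS+Y-S replicate 1 showed the first kind and held 27.4% of the variance. DS+Y-L replicates 1 and 2 scored 177 and 183 on it and replicate 3 scored -7.42, while the 3 ck libraries scored from -143 to -16.6. Between these ends the group means were 49.4 for the other 2 DS+Y-S libraries, 13.5 for Y-L, 0.655 for DS-L, -32.6 for Y-S and -39.1 for DS-S. The libraries of different groups overlapped, and a between-group share of the axis of 46.4% was reached by chance with permutation p = 0.159 (20000 permutations).

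**Figure D3:**
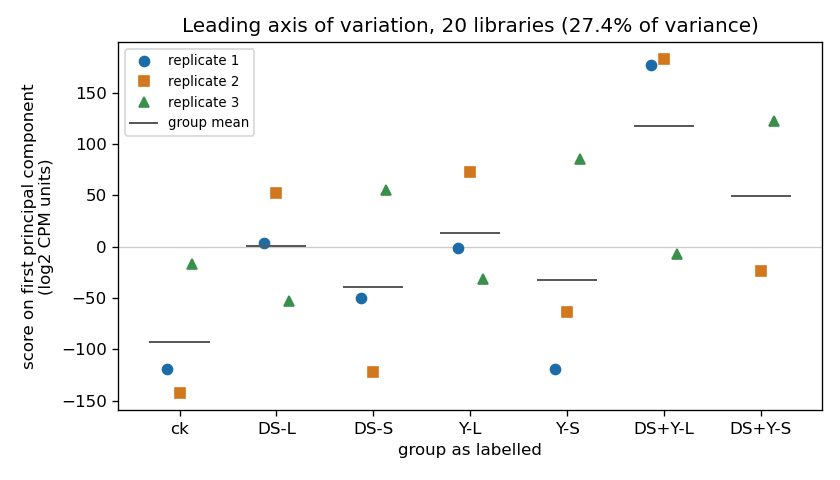
Score of 20 libraries on the first principal component of log2 CPM (27.4% of variance, y axis), by group (x axis), leaving out DS+Y-S replicate 1; marker shapes give the replicate number and lines the mean of each group. DS+Y-L replicates 1 and 2 score 177 and 183, and DS+Y-L replicate 3 scores -7.42.

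In 74 genes, DS+Y-L replicates 1 and 2 were the 2 highest libraries, at 5 CPM or more and at least 4-fold above each of the other 19. These genes took 2.64% and 3.09% of the counts of the 2 libraries. In DS+Y-L replicate 3 they took 0.0763%, inside the range of 0.0606% to 0.171% of the libraries of other groups. Of the 74 genes, 4 were among the 26 called in DS+Y-L against ck and 22 among the 32 called over the 7 groups. The selection was made after the data were seen, and it requires replicate 3 to lie at least 4-fold lower.

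**Figure D4:**
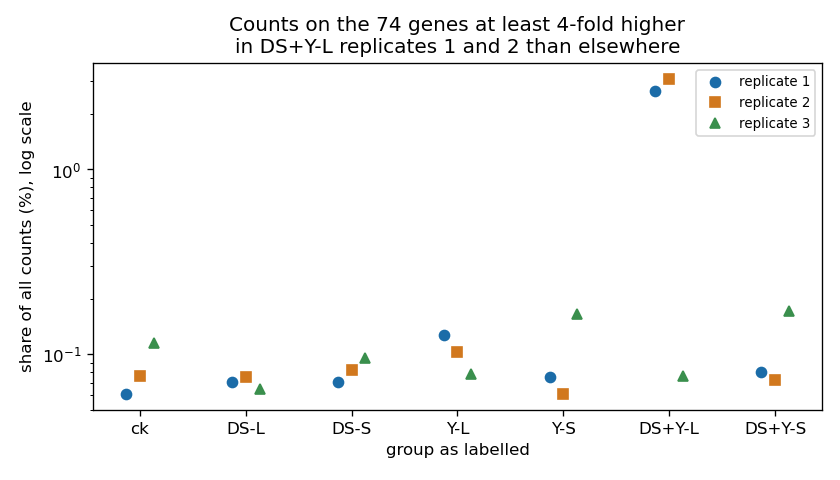
Share of all counts (%, log y axis) taken in each of the 21 libraries, by group (x axis), by the 74 genes at least 4-fold higher in DS+Y-L replicates 1 and 2 than elsewhere, with marker shapes for the replicate number. The 2 libraries the genes were selected on stand at 2.64% and 3.09%, and DS+Y-L replicate 3 at 0.0763%.

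DS+Y-S replicate 1 was of the second kind. Genes for which the other libraries predict between 20 and 40 counts were at 0 there in 34.2% of cases, against at most 5.50% in any other library. Genes with exactly 1 count numbered 489 in this library, against 4705 to 8533 in the others.

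**Figure D5:**
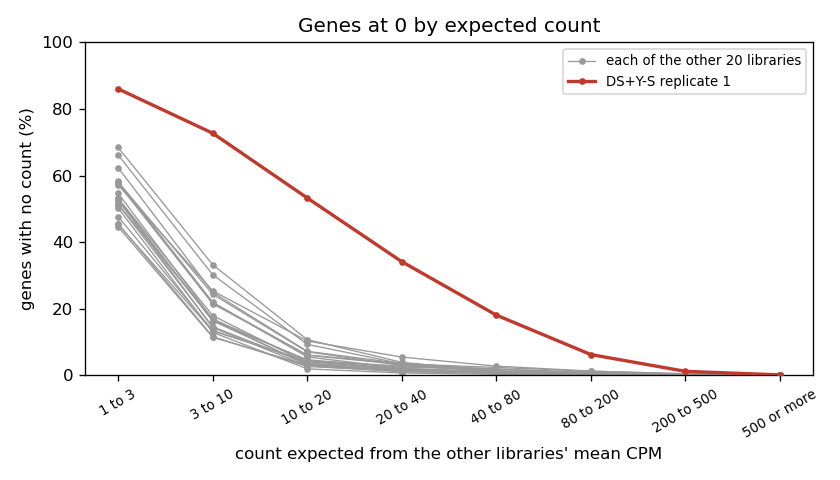
Share of genes with no count (%, y axis) by the count expected from the mean CPM of the other libraries (x axis), with 1 line per library. DS+Y-S replicate 1, drawn in red, holds 34.2% of genes at 0 where 20 to 40 counts are expected, and the other 20 libraries, in grey, at most 5.50%.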

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

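The tests on DS+Y-S replicate 1 and on the genes shared by 2 DS+Y-L libraries were chosen after the result was seen. The test of library overlap in the DESeq2 calls and the count over other splits were chosen before. Genes with 5 or more counts in 1 library and none in the other 20 numbered 4626 in DS+Y-S replicate 1, against at most 107 in any ck library. The same count was 194 in DS-L replicate 2 and 193 in DS+Y-L replicate 2. The low-count filter of the fit to all 21 libraries removes any gene counted in 1 library alone. By definition, then, none of them entered that fit (0 of the 4626, 0 of the 194 and 0 of the 193). The fits without that filter include them.

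DS+Y-S replicate 1 has counts on the fewest genes, 36755, although its total of 17205301 counts lies inside the range of the other libraries. RNA of another organism in place of the plant's is argued against, because 0.148% of the genes expected at 500 or more counts are at 0 there (exact 95% interval 0.0738% to 0.264%), and so is an effect of the DS+Y-S treatment on all its libraries, since the lower of its other 2 libraries has 53196 genes, above the lowest library of the other groups at 47279. Another genotype of the plant stays open, because it would keep the abundant genes and the 4626 genes seen only there could go with it. A candidate explanation is that this library was read from fewer distinct RNA fragments, each counted many times. Its zeros give 23.3 counts per fragment and its mean count on rare genes gives 23.5, against at most 5.61 and 3.76 elsewhere. This would leave 737000 fragments against 3020000 or more. The 4626 genes seen only there had a median of 21 counts, and rare fragments counted many times could account for them. But they are among the rare genes behind the 23.5, so their counts are no separate support. The 23.5 was not computed without them.

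DS+Y-L replicates 1 and 2 share 74 genes at least 4-fold above every other library, while no other of the 210 pairs of libraries has more than 34. Replicate 3 was the next highest in 2.70% of them, where chance gives 5.26%, but the selection itself sets replicate 3 at least 4-fold lower, so this cannot test whether the treatment acted alike in its 3 libraries. Most of the 74 are not confined to the 2 libraries, since 93.2% have counts in 10 or more of the other 19. The ratio to those varies over genes, with log2 quartiles of 4.22 and 6.61. But the low-count filter had removed genes confined to the 2 libraries before the selection. RNA of another organism in the 2 libraries therefore stays open. A single library under both labels is argued against by a chi-square per degree of freedom of 62.0. Also open and not tested are the treatment itself and a difference between leaves within the DS+Y-L group, such as how far the stress had advanced. So is a wrong label on replicate 3, whose most similar library is Y-L replicate 1 (r = 0.950). Only 6 of the 21 libraries had their most similar library in their own group.

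DESeq2 called 2795 genes in DS+Y-L against ck where edgeR called 26. Calls that rest on single libraries were sought by overlap: the libraries of the groups did not overlap in 80% of the DESeq2 calls, against 23.2% of all tested genes and 10% by chance, and this meets neither bound set beforehand, so it leaves open how many rest on single libraries. The 10 splits of the 6 libraries are too few for a share under 0.05; 1 split, the real one, reached 2795 and the highest other gave 1768. That split exchanged ck replicate 3 with DS+Y-L replicate 3, so DESeq2 also called many genes when DS+Y-L replicates 1 and 2 were set against the remaining libraries with 1 ck library on their side.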

How the results depend on the processing

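The fit by limma-voom with library weights, the robust spread, the removal of DS+Y-S replicate 1 from contrasts it is not part of, mean log2 CPM in place of fitted changes, and the 7 contrasts averaged over groups were chosen after seeing the data. Of the counts of calls, 72 moved by over 1.5 times under another setting and 114 did not. With single libraries left out and the filter applied again, 50 moved and 163 did not. Where edgeR called 0 genes, any call counts as moved. The log2 fold minimum of 1 makes up 23 of the 114, and it only removes calls, so it could not move a count of 0. In DS+Y-L against ck its outcome was also fixed, since the smallest called log2 change was 1.64 in size. The cause was not tested except where stated.

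Unchanged or within 1.5 times were all counts with DESeq2 size factors (28 for DS+Y-L against ck, 33 for the 7 groups), a log2 fold minimum of 1, and the robust spread (26 and 25). The 4 correlations for adding a treatment, at 0.262, 0.259, 0.0267 and -0.0294, were 0.354, 0.320, 0.0194 and -0.00555 over genes with a mean of 10 CPM or more, and 0.297, 0.268, 0.0164 and -0.0289 from mean log2 CPM. Each moved by less than 1 SD over regroupings of the libraries, which was 0.185 to 0.236. That SD is nearly as large as the correlations at suffix L and larger than those at suffix S. Staying within it is therefore a loose bound that says little about the effect of the processing. Contrasts of which DS+Y-S replicate 1 is not part were fitted without it, on 41105 genes that passed the filter applied again. DS+Y-L against ck then had 45 calls, all 26 genes among them, and no other count moved.

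DESeq2 called 2245 genes over the 7 groups by the likelihood ratio test. Its Wald test against ck called 493 for DS-L, 97 for DS-S, 274 for Y-L, 79 for Y-S, 2795 for DS+Y-L and 355 for DS+Y-S. It called 646 for DS+Y-L against DS-L, 435 against Y-L and 482 against DS+Y-S. It called 40 for DS+Y-S against DS-S, 18 against Y-S, 91 for DS-L against DS-S and 15 for Y-L against Y-S. Departures from additivity numbered 81 at L and 55 at S, L against S averaged 539, and all treated against ck 415. Over both suffixes it called 309 for DS, 232 for Y and 1290 for DS+Y against ck, 717 for DS+Y against DS and 622 against Y.

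Without a low-count filter, the 7 groups gave 9331 calls. Against ck there were 1601 for DS-L, 762 for DS-S, 1274 for Y-L, 615 for Y-S, 3930 for DS+Y-L and 1525 for DS+Y-S. DS+Y-L gave 2026 against DS-L, 1733 against Y-L and 1612 against DS+Y-S. DS+Y-S gave 1000 against DS-S and 692 against Y-S, DS-L 499 against DS-S and Y-L 308 against Y-S. Additivity gave 818 at L and 729 at S, L against S 1561 and all treated against ck 2259. Over both suffixes DS, Y and DS+Y gave 1469, 1124 and 3046 against ck, and DS+Y 2223 against DS and 1910 against Y. Of the 3930 in DS+Y-L against ck, the only contrast split this way, 3814 pass the filter and 116 do not.

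The limma-voom fit called 4247 genes over the 7 groups, 4670 for DS-L, 2 for Y-L, 2946 for DS+Y-L and 1 for DS+Y-S against ck. It called 4104 for DS+Y-L against DS-L, 22 against Y-L, 1 for DS+Y-S against DS-S, 1 against Y-S and 4094 for DS-L against DS-S. Additivity at L gave 1, L against S 979 and all treated against ck 290. Over both suffixes DS, Y and DS+Y gave 479, 1 and 443 against ck, and DS+Y 966 against DS and 86 against Y. Its weights ran from 0.104 for DS+Y-S replicate 1 to 12.8 for DS-L replicate 1.

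With the replicate number as a replicate block, the 7 groups gave 8 calls, DS+Y-L against ck 0 and all treated against ck 1, and no other count changed. The numbers do not pair the samples, because 18 of 63 pairs with the same number deviated together at r over 0.1, with r from -0.366 to 0.496, and 4 of 21 libraries correlated best with their own number. Only the 6 libraries compared gave 0 calls for DS+Y-L against ck, 7 for DS-L, 8 for Y-L and 8 for Y-S. Fewer libraries stood behind each estimate of the spread, and the filter, applied again, left 28411 to 30761 genes.

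With each library of a comparison left out in turn, and no library outside it, calls ranged from 2 to 558 for the 7 groups and from 0 to 1735 for DS+Y-L against ck. They ranged from 0 to 500 for DS+Y-L against DS-L, 0 to 438 against Y-L and 0 to 211 against DS+Y-S. They ranged from 0 to 1 for DS+Y-S against ck, 0 to 2 for DS-L against DS-S, 0 to 15 for DS-L against ck, 0 to 88 for additivity at L, 0 to 30 for L against S and 0 to 26 for all treated against ck. Over both suffixes they ranged from 0 to 87 for DS+Y against ck, 0 to 489 against DS and 0 to 361 against Y. The highest was without DS+Y-L replicate 3 for all of these except DS+Y-S against ck, both DS-L contrasts and all treated against ck, where it was without DS+Y-S replicate 1, DS-L replicate 3 and DS-S replicate 1. The remaining counts stayed at 0 in these fits.

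The 4 named genes kept their direction in all 15 settings. Log2 fold changes ranged from 9.73 to 12.07 for TRINITY_DN45062_c0_g1 and 5.69 to 6.51 for TRINITY_DN26884_c0_g1. They ranged from -3.60 to -2.64 for TRINITY_DN3050_c1_g1 and -3.68 to -2.92 for TRINITY_DN651_c1_g1. In that order they passed the threshold in 8, 10, 8 and 8 settings, with adjusted p up to 0.272, 0.226, 0.272 and 0.281. The lowest, 3.99e-52, 5.46e-23, 1.25e-07 and 4.32e-10, all came from edgeR without a low-count filter. The main edgeR fit gave 0.0398, 0.0133, 0.0398 and 0.0465. The block ended the call of all 4 (edgeR adjusted p from 0.0604 to 0.0852), and so did the 6-library fit (0.0701 to 0.0965).

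Correlations over genes called in either contrast were not run, since edgeR called none in these contrasts. Tests of gene lists were not run because 0 genes matched a description, and a pseudocount did not apply to counts. Total counts, at 16431940 to 20138058, set no library far apart in depth. The spread between libraries has a coefficient of variation of 0.619 beyond counting error, which more counts would not lower.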

Other observations

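The tests on pairs of libraries and on the direction of called genes, and those of the leading axis against groups and genes detected, were chosen after the result was seen. The tests of the axis against total counts, effective length and replicate number, and the splits of the samples, were chosen before. The 7 contrasts averaged over groups were themselves added after the data were seen.

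Genes in which 2 libraries stand above the other 19 by at least 4-fold numbered 138 over all pairs, and only 11 of the 210 pairs had any. DS+Y-L replicates 1 and 2 held 74 of them, with a median of 72.5 CPM in the 2 libraries and 1.10 CPM in the others. DS+Y-L replicate 1 and DS+Y-S replicate 2 shared another 34, which took 0.424% and 0.466% of their counts and at most 0.0563% in the other 19 libraries. Y-S replicate 1 and DS+Y-S replicate 2 shared 9. At 2-fold the leading pair held 241 of 519 genes and at 8-fold 25 of 40. Genes in which the same 2 DS+Y-L libraries lay at least 4-fold below the others numbered 7 of 11.

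The 26 genes called in DS+Y-L against ck were followed in contrasts that share none of its libraries. In DS-L against DS-S, 22 of the 26 differed in the direction they had in DS+Y-L against ck, and 4 of the 20 ways of assigning those 6 libraries gave as many (exact one-sided p = 0.2). In Y-L against Y-S it was 19 (exact one-sided p = 0.25). In DS+Y-S it was 20 against DS-S (exact one-sided p = 0.2) and 20 against Y-S (exact one-sided p = 0.15). The smallest p these designs allow is 0.05.

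The 7 contrasts of group means run on the leading axis gave 1 unadjusted value under 0.05. The 5 DS+Y libraries averaged 105 above the 12 single-treatment libraries (exact p = 0.0259, two-sided), which became 0.154 after Benjamini-Hochberg adjustment over the 7. All treated libraries averaged 109 above ck (exact p = 0.0658, adjusted 0.154) and L libraries 51.3 above S (exact p = 0.224, adjusted 0.262). Over 20 libraries, the axis correlated with genes detected at Pearson r = -0.524 (permutation p = 0.0175, adjusted 0.0677 over 4 relations) and Spearman rho = -0.477 (permutation p = 0.0338, adjusted 0.0677), and r was -0.362 without the 2 farthest libraries. With total counts it gave r = -0.131 (permutation p = 0.58, adjusted 0.58) and rho = -0.17 (permutation p = 0.466, adjusted 0.58), and r was -0.0202 without the 2 farthest and at most 0.265 in size with any 1 library left out. Across genes, which are not independent replicates, loadings on the axis correlated with log2 effective length at r = -0.00557. Replicate numbers held 3.29% of the axis (permutation p = 0.75), at most 13.2% with any 1 library left out, and group labels 46.4% (permutation p = 0.159).

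Other splits of the samples bear on each count of calls. For the 7 groups together, 3 of 25 splits, the real one included, gave as many as the real 32, with 63 the highest other, so chance was not excluded. For the departures from additivity at L and S, the contrast of L with S, and all treated groups against ck, all 25 of 25 splits reached the real 0, with 4, 0, 1 and 1388 the highest others. The same held for DS, Y and DS+Y against ck over both suffixes, with 0, 0 and 258 the highest others, and for DS+Y against DS and against Y, with 12 and 2. Splits that call 1388 and 258 genes where the real one calls 0 point to a structure of the samples, and which libraries carry it was not tested. A count of 0 is reached by any split, so these say nothing of chance. Each contrast of 2 groups has 10 splits, too few for a share under 0.05. For DS+Y-S against Y-S all 10 splits had as many genes at an unadjusted p under 0.05 as the real one. For DS+Y-L and Y-L against ck only the real split reached its own unadjusted count, and the other contrasts lay between. In DS+Y-L against ck the real value was 26 calls, reached by 1 split, and the highest other 2. The other 12 contrasts had a real value of 0, reached by all 10 splits. Their highest others were 1484 for DS+Y-L against DS+Y-S, 38 for DS+Y-L against Y-L, 13 for DS+Y-L against DS-L, 7 for DS+Y-S against ck, and 0 for the remaining 8. The split with 1484 set DS+Y-L replicates 1 and 2 and DS+Y-S replicate 3 against the other 3 libraries, and the splits with 38 and 13 moved DS+Y-L replicate 3 to the other side.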
